A study of Rattus norvegicus with 8 samples.

How the data were processed

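RNA sequencing of lung tissue from 8 Sprague Dawley rats was taken from the deposited files. Per the labels' protocols, total RNA was isolated with a lysis reagent and depleted of ribosomal RNA, and the libraries followed the sequencing supplier's standard preparation. The group of each rat, MCT or MCT with DMB, and its replicate number, 1 to 4, came from the sample titles and treatment labels, and each library is named in the labels after a different rat.

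The authors deposited whole-number read counts per Ensembl gene for the 8 libraries in 1 table, with the exon coordinates of each gene. The submitters' processing notes name bcl2fastq, fastp 0.20.1, HISAT2 2.2.1, SAMtools 1.11, featureCounts of Subread 2.0.1 and DESeq2 1.28.1, with the rn6 and Rnor_6.0 builds, and give no order or settings for them. Whether counting used strand and how reads matching several places were treated is not given in the sources used here. This matters for overlapping genes and for near-identical copies, whose counts can then be shared or lost. Of the 38 genes called by edgeR, 2 have a span that overlaps another gene. Per the file headers, the table also gives a length for each gene, which is the deposited summed length of its merged exons in bases. The authors also deposited 1 file per rat with expression values on a log2 scale. Their normalization is not stated in the headers. The regularized log of DESeq2, computed blind to the groups from the deposited counts, gave these values within 5e-09 at most for all genes with a count, and 100% lay within 0.01. The version that uses the groups gave 87.9% within that tolerance. In each rat, the deposited log2 values matched the count column of the same name best across genes, with correlations of 0.876 to 0.92 after centring against at most 0.386 for any other library.

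The count table held 32883 genes, of which 9373 had no count in any library, and no row that was not a gene. Genes were kept with filterByExpr of edgeR at its default minimum count of 10, which left 14973. Library sizes were scaled with TMM factors. The main test was the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with MCT with DMB against MCT and no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 0.207. CPM and log2 CPM used the same factors, with a prior count of 3 for log2 CPM. Tests of a single value per rat were exact two-sided permutation tests, for which 0.0286 is the smallest p with 4 rats per group. Intervals for a ratio of summed counts are exact 95% Poisson intervals and cover counting error only. Total counts of 9456000 to 11843731 per library put a gene at 1 CPM at about 10 reads.

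No pair of replicates looked like 1 library deposited more than once. Over the 12 pairs within groups, chi-square per degree of freedom ran from 14.1 to 43.1, where sampling noise alone gives about 1. All 8 libraries had counts on the Y chromosome, from 2820 to 4116.

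Gene symbols could not be assigned. The reference table used here, of assembly GRCr8, paired 0 of the 32883 identifiers with a name, and the files pair none either. For this reason the 34 gene lists fixed before the data were examined, covering lung cell types, inflammation, vascular signalling and trimethylamine metabolism, were not tested. The rule for named genes was also fixed before the data were examined. It took the 10 largest changes in each direction among called genes with a symbol and separated groups, members of the lists, and a few genes by symbol. It was reduced to the 2 identifiers with the largest positive and the 2 with the largest negative log2 fold change among called genes with separated groups. Positions are those of the count table, in Rnor_6.0, counted from 1.

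In place of the lists, regions and gene classes were examined, all chosen after the data were seen. These were 28 sets (chromosomes with at least 5 tested genes, and classes of exon number or of exonic length under 500 or over 5000 bases) and 1114 windows of 500 kb with at least 5 tested genes. Both were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry. Fisher's exact test compared the share of called genes on each chromosome with the rest for edgeR and for DESeq2. Runs of at least 3 neighbouring genes called by DESeq2 in 1 direction were compared with 1000 shuffled gene orders, and the correlation of signed z scores between neighbouring genes with 1000 shuffles. The count of DESeq2 calls on chromosome 2 was compared with 10000 rotations of the calls along the genome.

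Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile factors, library size alone, no low-count filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, 1 surrogate variable of sva 3.50.0, the test without the robust option, an adjusted threshold of 0.1, a log2 fold change of at least 1, and each library left out in turn. Alternatives added later were limma on the deposited log2 values, DESeq2 and limma-voom with each library left out, DESeq2 with the block, and all those on the windows. An adjusted p that DESeq2 left undefined, as for 344 genes, was kept out of its counts. The edgeR and DESeq2 tests, the windows and the correlation of neighbours were also run on the 35 splits of the 8 libraries into groups of 4.

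The tests were tested on simulated counts with the means, dispersions and library sizes of these libraries and a set of changed genes. The changed genes were drawn only from genes above a minimum mean CPM, so recovery among the genes of lowest count was not measured. In the comparison of MCT with DMB against MCT, edgeR ran on 14820 simulated genes and recovered 20 of 67 genes changed 1.5-fold, 56 of 67 changed 2-fold and 62 of 66 changed 4-fold, and called 14 unchanged genes. DESeq2, on 14973 genes, recovered 27, 64 and 66 of them and called 53 unchanged genes. limma-voom, on 14820 genes, recovered 16, 53 and 64 and called 9 unchanged genes. A simulated window of 20 genes raised together was called by camera, and 0 other windows were. Simulated genes varied independently between rats, whereas the windows called in the real data had estimated correlations of 0.806 and 0.562. The simulation therefore does not measure false calls of windows whose genes vary together.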

Results

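Lung RNA was compared between rats given monocrotaline (MCT) alone and rats given MCT together with 3,3-dimethyl-1-butanol (DMB). MCT is a plant alkaloid that injures the pulmonary vessels of rats and is used to produce pulmonary hypertension. DMB inhibits the bacterial formation of trimethylamine, the precursor of trimethylamine N-oxide, the metabolite named in the title of the series. Each group held 4 Sprague Dawley rats, with 1 library per rat. The libraries were made from total RNA after removal of ribosomal RNA, so that messenger and noncoding transcripts were both open to counting. No library from rats without MCT was analysed here, and every value below therefore compares lungs that had all been exposed to MCT.

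Depth was similar in the groups. The DMB libraries, replicates 1 to 4, held 10922565, 10217687, 11843731 and 9456000 counts, and the MCT libraries held 10206835, 10189786, 10950119 and 10920155. The mean total was 10610000 ± 1017000 with DMB and 10570000 ± 425600 without (SD, n = 4 each; exact two-sided permutation test, p = 0.829). Between 19183 and 20250 of the 32883 genes in the table had at least 1 count in a given library, and 14973 genes had enough counts to be tested.

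The comparison asked which lung transcripts differed when DMB was added to MCT. Expression differed for 38 of the 14973 tested genes, of which 13 rose and 25 fell with DMB (edgeR quasi-likelihood test, adjusted p under 0.05, n = 4 per group). The median log2 fold change was 0.89 among the genes that rose, with a range of 0.53 to 2.09, and -1.02 among the genes that fell, with a range of -0.48 to -4.72. A change of at least 2-fold was reached by 5 of the genes that rose and by 13 of those that fell. Mean abundance of the 38 genes ran from 1.86 to 585 CPM (read counts scaled to library size), with a median of 30.8. In each of the 38 genes all 4 DMB values lay on one side of all 4 MCT values. Over all tested genes such a separation was seen for 1373, or 9.17%, where unrelated groups of 4 and 4 would give 2.86%, and 621 of these lay higher with DMB and 752 lower.

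The genes that changed were spread over the genome. They lay on 16 chromosomes, with 3 higher and 3 lower on chromosome 2, 2 higher and 2 lower on chromosome 1, and 1 higher and 3 lower on chromosome 3. Chromosomes 4, 8 and 9 each held 3 genes that fell and no gene that rose. No gene on the X, Y or mitochondrial chromosome passed the edgeR test, while DESeq2 called 14 X-linked genes as higher and 9 as lower. Genes of 2 to 5 exons accounted for 4 of the genes that rose and 9 of those that fell. Genes of 20 or more exons accounted for 2 that rose and 1 that fell, and none of the 961 single-exon genes passed. No chromosome and no class of exon number or exonic length was shown to move as a set. With camera 0 of the 28 sets passed the adjusted threshold, with a preset or an estimated correlation. The smallest unadjusted camera p with the preset correlation was 0.0169, for the mitochondrial chromosome (adjusted p = 0.286). At unadjusted p under 0.05 edgeR gave 2584 genes, 1166 higher and 1418 lower, against 749 expected by chance.

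**Figure D1:**
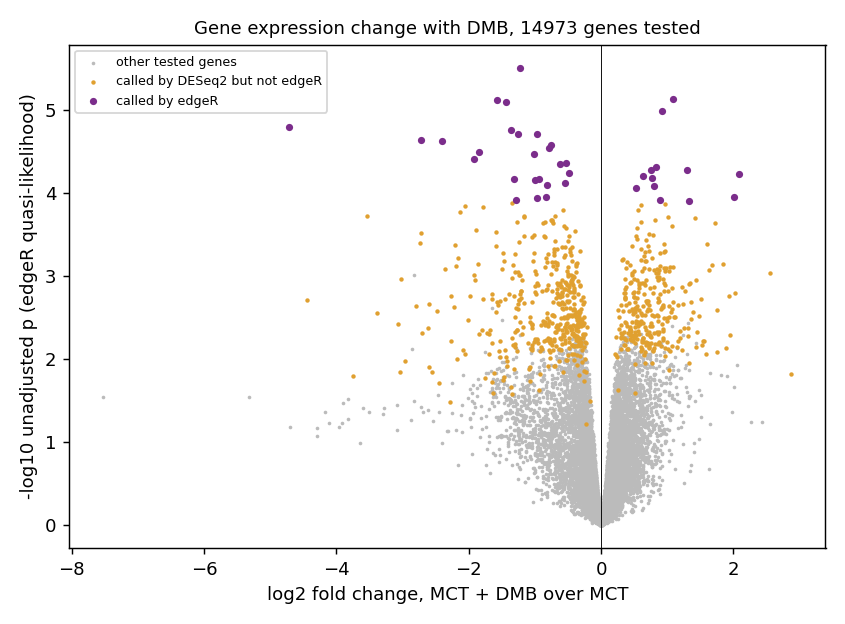
Each point is 1 of the 14973 tested genes, with its log2 fold change (MCT + DMB over MCT) on the x axis and the -log10 of its unadjusted edgeR p on the y axis. The 38 genes called by edgeR are purple, the 721 called by DESeq2 and not by edgeR are orange, and more of both kinds lie to the left of 0 than to the right.

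The count table pairs no gene symbol with its Ensembl identifiers, so the called genes with the largest changes are given by identifier and position in Rnor_6.0. Among the 38 genes called by edgeR, the steepest fall belonged to ENSRNOG00000011824, a gene of 3 exons and 1391 exonic bases on the minus strand of chromosome 4 from 124110716 to 124113242. Its level was 4.72 ± 1.81 CPM without DMB and 0.175 ± 0.185 CPM with DMB (SD, n = 4 each). The log2 fold change was -4.72 with a standard error of 0.61 (edgeR adjusted p = 0.0318). The MCT libraries held 34 to 70 reads of it and the DMB libraries 0 to 4, or 196 against 7 reads in total. That is a ratio of 28.1 with a 95% interval of 13.4 to 70.7 for counting error alone. The size of the fall depended on DMB replicate 4, which held 4 of these 7 reads, and the log2 fold change of ENSRNOG00000011824 was -5.52 without it (edgeR adjusted p = 0.0404). The next largest fall among them was that of ENSRNOG00000007765, a gene of 7 exons and 2737 exonic bases on the minus strand of chromosome 3 from 67635607 to 67668772. It fell 6.6-fold, from 56.5 ± 29.3 to 8.55 ± 1.4 CPM, with a log2 fold change of -2.72 ± 0.34 (SE; edgeR adjusted p = 0.0318).

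The 2 largest rises among the genes called by edgeR were on chromosome 1. ENSRNOG00000010938, on the plus strand from 91433030 to 91448564 with 11 exons and 1877 exonic bases, rose 4.26-fold, from 5.27 ± 0.81 to 22.5 ± 10.6 CPM (SD, n = 4 each). Its log2 fold change was 2.09 ± 0.3 (SE; edgeR adjusted p = 0.0365). Its span overlaps that of 1 other gene in the table, and whether counting used strand is not given in the sources used here. ENSRNOG00000020117, on the plus strand from 220325352 to 220334615 with 10 exons and 1260 exonic bases, had 0.73 ± 0.156 CPM without DMB and 2.98 ± 0.771 CPM with DMB. Its log2 fold change was 2.0 ± 0.32 (SE; edgeR adjusted p = 0.0484), from 5 to 9 reads per MCT library and 22 to 35 per DMB library. DESeq2 gave adjusted p of 3.33e-09 and 4.61e-14 for the 2 genes that fell and 4.12e-08 and 0.000309 for the 2 that rose. With 1 library left out, edgeR still called ENSRNOG00000011824 in 4 of 8 fits, ENSRNOG00000007765 in 3, ENSRNOG00000010938 in 2 and ENSRNOG00000020117 in 0, with adjusted p of at most 0.15 and no change of sign.

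**Figure D2:**
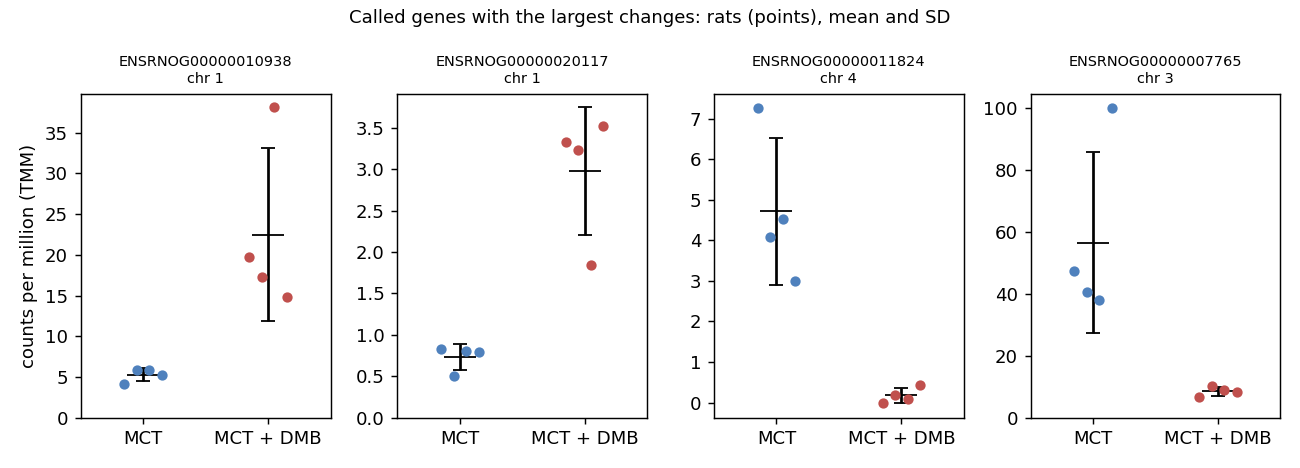
CPM in each rat of the 2 genes with the largest rises and the 2 with the largest falls among those called by edgeR (points, n = 4 per group), with the group mean and SD (horizontal mark and bars). The MCT and MCT + DMB rats are separated in each panel, and the y scales differ between panels.

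The number of genes called depended on the tool and on single libraries. DESeq2 called 759 genes, 309 higher and 450 lower, with median log2 fold changes of 0.70 and -0.70, and limma-voom with sample quality weights called 30, of which 7 were higher and 23 lower. All 38 edgeR genes were among the DESeq2 calls with the same sign, and 28 of them passed all 3 tools. Of the DESeq2 calls, 620 (81.7%) had separated groups. In the simulated counts DESeq2 called 53 unchanged genes beside 27, 64 and 66 changed ones. There edgeR called 14 unchanged genes beside 20, 56 and 62, and limma-voom 9 beside 16, 53 and 64. The share of false calls exceeded the threshold of 0.05 for each of the 3 tools, most so for DESeq2. Their adjusted p values and numbers of calls carry that limit. Without DMB replicate 1 edgeR called 0 genes, although 2034 had an unadjusted p under 0.05 and DESeq2 called 424. Without DMB replicates 2, 3 and 4 edgeR called 22, 4 and 24 genes, and without MCT replicates 1, 2, 3 and 4 it called 6, 21, 30 and 15. DESeq2 called fewer genes by over 1.5 times without DMB replicate 1 (424), DMB replicate 3 (346) and MCT replicate 4 (473). Each of its 8 fits with a library left out kept all 38 edgeR genes. These 38 were chosen with all 8 libraries and all had separated groups, so their retention is not separate evidence.

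**Figure D3:**
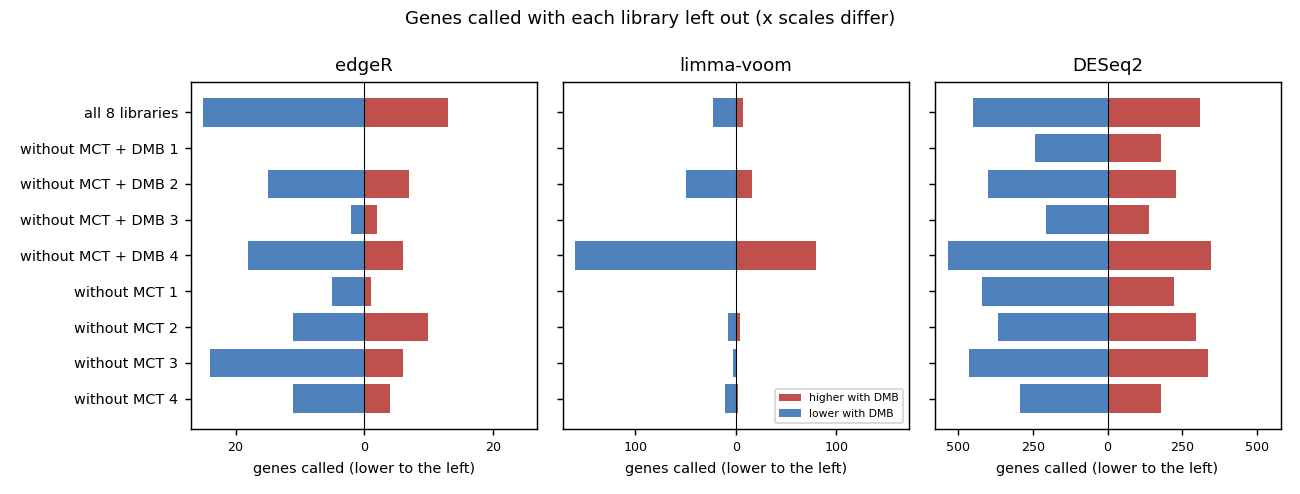
Number of genes called higher (red, to the right) and lower (blue, to the left) with DMB by edgeR, limma-voom and DESeq2, with all 8 libraries and with each left out; the x scales differ between panels. edgeR ranges from 0 to 30 genes, limma-voom from 0 to 240 and DESeq2 from 346 to 878 when a library is left out.

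Across whole libraries, the first principal component of log2 CPM held 35.1% of the variance and placed the 4 DMB rats at -30.8, -3.81, -35.5 and -16.7 and the 4 MCT rats at 3.76, 13.3, 13.4 and 56.4. The groups did not overlap on it (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give; 0.172 after Benjamini-Hochberg adjustment over 6 library measures).

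Short genes in a stretch of chromosome 17 lay higher with DMB in most of their point estimates. The genome was divided into windows of 500 kb, and 2 of the 1114 windows with at least 5 tested genes passed camera with its preset correlation. Both calls were lost with an estimated correlation (camera unadjusted p = 0.302 for the window at 44500001 and 0.305 for that at 43500001, adjusted p = 0.991 for both with an estimated correlation). In the window from 44500001 to 45000000, all 21 tested genes had a positive log2 fold change, with a median of 0.42 (camera adjusted p = 0.0231 with the preset correlation), and 18 of them had a single exon. In the window from 43500001 to 44000000 it was 26 of 27 genes, with a median of 0.40 (camera adjusted p = 0.0446 with the preset correlation), and 19 had a single exon. Of the 48 genes, 28 were single-exon genes of exactly 312, 381, 393 or 411 exonic bases. None of the 48 was called on its own by edgeR or DESeq2, and an unadjusted edgeR p under 0.05 was reached by 2 genes of the window at 44500001 and 4 of the other. Averaged over each window, log2 CPM was 4.14 ± 0.39 with DMB and 3.70 ± 0.43 without for the window at 44500001, and 4.89 ± 0.28 and 4.54 ± 0.33 for the other (SD, n = 4 each; exact two-sided permutation test, p = 0.2 and 0.114). These differences of 0.43 and 0.35 became 0.25 and 0.21 without DMB replicate 4 and 0.23 and 0.20 without MCT replicate 4, and 0 windows were called without either library or without MCT replicate 2.

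**Figure D4:**
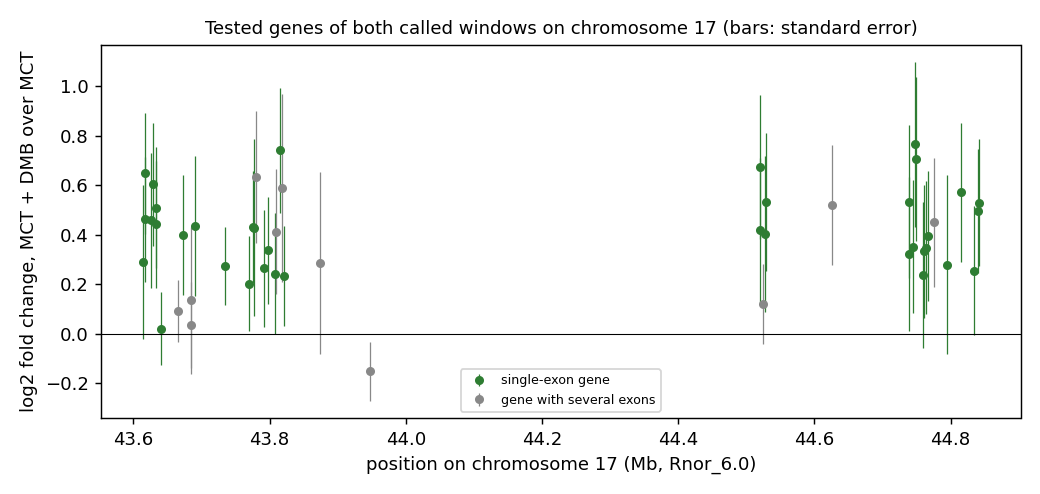
Log2 fold change (MCT + DMB over MCT) of the 48 tested genes of both windows against their position on chromosome 17 in Mb (Rnor_6.0), with bars for the standard error; green points are single-exon genes. Of these estimates 47 lie above 0, and none of the genes was called on its own.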

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

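All tests of windows in this part were chosen after the data were seen, and the test with an estimated correlation and the comparison of window with outside genes per rat were chosen after the results they bear on were known.

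A single rat stood far from the other 3 of its group in 4 of the 28 sets of 4 values examined, where chance gives about 1.4. DMB replicate 3 had the most counts on the Y chromosome, 4116, against 3231 to 3364 in the rest of its group. It was also the deepest library, and as a share of all counts it had 0.0348%, close to the 0.0342% of DMB replicate 4. MCT replicate 4 had 99.9 CPM of ENSRNOG00000007765 against 37.8 to 47.4 in the other MCT rats. MCT replicate 2 had 0.497 CPM of ENSRNOG00000020117, from 5 reads, against 0.795 to 0.83. DMB replicate 4 had a mean log2 CPM of 5.31 over the chromosome 17 window at 43500001, against 4.73 to 4.78 in the other DMB rats.

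For the count of 2 windows, chance assignment of rats is not excluded. Of the 35 splits of the libraries into 4 and 4, 21 called at least as many windows anywhere in the genome. The real split called 2 and the highest other 7. How often the splits called the 2 windows of chromosome 17 themselves was not counted. Variation that the genes of a window share between rats is consistent with the calls, since estimated correlations of 0.806 and 0.562 raised the camera p to 0.302 and 0.305. Recovery of short single-exon transcripts stays open: the 360 such genes under 500 bases outside the windows had a median log2 fold change of 0.17 (95% interval 0.11 to 0.22) and those in the windows 0.43 (0.38 to 0.51). The bound set beforehand, a median outside below the window interval, was met, but that interval treats genes as independent, which the correlations above rule out, and per rat the difference was 0.33 with a standard error of 0.22 (exact permutation p = 0.143). A response of these genes to DMB stays open as well.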

How the results depend on the processing

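The fits on the deposited log2 values, DESeq2 and limma-voom with a library left out, DESeq2 with the block, and all tests of windows were chosen after the data were seen. The cause of a change was not tested except where the setting itself gives it. edgeR called 38 genes, 13 higher and 25 lower. The total stayed within 1.5 times with RLE factors (39), upper-quartile factors (40), library size alone (55, with 22 higher), a filter of 1 CPM (40), no robust option (37), limma on the deposited log2 values (54) and limma-voom (30, with 7 higher). It moved further with DESeq2 (759, 309 higher and 450 lower), without a low-count filter (100, 33 and 67), with 1 surrogate variable (6, 1 and 5), and by construction at an adjusted threshold of 0.1 (342, 136 and 206) and a log2 fold change of at least 1 (18, 5 and 13). With each library left out edgeR gave 0 to 30 genes (0 to 10 higher, 0 to 24 lower), DESeq2 346 to 878 (139 to 344 higher, 207 to 534 lower) and limma-voom 0 to 240 (0 to 80 higher, 0 to 160 lower), in fits that had fewer rats. limma-voom gave 0 without DMB replicate 1, DMB replicate 3 or MCT replicate 1, and 240 without DMB replicate 4.

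No pairing of the rats by replicate number was seen in expression. Same-numbered libraries had correlations of deviations of 0.111, -0.129, 0.0165 and -0.07, and not every library correlated best with its own number. So few pairs cannot exclude that equal numbers mark a shared litter or day. With the replicate block edgeR called 19 genes, 8 higher and 11 lower, of which 6 were among the 38, and DESeq2 called 672, 284 higher and 388 lower, which included all 38. No window was called with the block (0).

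The 4 named genes kept their sign in all 20 alternatives each. ENSRNOG00000011824 stayed past the threshold in 15, ENSRNOG00000007765 in 14, ENSRNOG00000010938 in 11 and ENSRNOG00000020117 in 8, with the highest adjusted p at 0.0931, 0.109, 0.142 and 0.15. On the deposited log2 values, which are shrunken by construction, their log2 differences were smaller, at -0.59, -1.47, 0.93 and 0.29 in the same order. The 2 windows remained with RLE factors, library size alone and a filter of 1 CPM. The count was 0 with an estimated correlation and with fry, 1 with windows of 250 kb (on chromosome 18) and 4 with windows of 1 Mb, of which 2 were on chromosome 17. With a library left out it ran from 0 to 3. The analyses of protein-coding genes alone and of the fixed gene lists were not run, since no symbols or gene types could be assigned. At these depths, the simulated test recovered 20 of 67 changes of 1.5-fold, all in genes above a minimum mean CPM. Changes of that size were thus often not detectable at this depth and number of rats, and recovery among genes of lower count was not measured.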

Other observations

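All tests in this part were chosen after the data were seen, apart from edgeR, DESeq2 and the splits of their calls.

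Mitochondrial transcripts did not pass any adjusted test, and their point estimates above 0 rested in part on single rats. With all libraries, the 16 tested genes of the mitochondrial chromosome each had a positive log2 fold change, with a median of 0.25 and 0.25 to 0.28 under the other scalings, and 0 were called by edgeR or DESeq2 (smallest edgeR adjusted p = 0.21). The number above 0 was 12 without DMB replicate 1 (median 0.12), 13 without DMB replicate 4 (0.17) and 13 without MCT replicate 3 (0.12). As a set they had a camera p of 0.0169, an adjusted p of 0.286, and an unadjusted p of 0.45 with an estimated correlation. Their share of all counts was 2.18% ± 0.718 with DMB and 1.68% ± 0.307 without (SD, n = 4 each; exact two-sided permutation test, p = 0.229). DMB replicate 1 had 3.21%, and without it the DMB mean was 1.84% and the difference 0.16 percentage points in place of 0.502. The gene from 1094 to 2664 took 0.774% ± 0.436 with DMB and 0.429% ± 0.148 without (exact permutation p = 0.229), with 1.36% in DMB replicate 1 and a DMB mean of 0.577% without it. This gene held most of the difference in share. The other genes of the mitochondrial chromosome together took 1.41% ± 0.33 with DMB and 1.25% ± 0.231 without (exact permutation p = 0.457). Their difference was 0.158 percentage points, and 0.0112 without DMB replicate 1. The most counted gene of all, on chromosome 14 from 46523594 to 46529375, took between 1.13% and 4.77% of the counts of a library.

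Chromosome 2 held a larger share of DESeq2 calls than the rest of the genome by Fisher's exact test, though not after rotation of the calls. DESeq2 called 73 of its 946 tested genes (7.72%), 28 higher and 45 lower, against 4.89% elsewhere (Fisher's exact test, p = 0.000298, 0.00715 after adjustment over 24 chromosome classes). Such a test takes neighbouring genes as independent. Of 10000 rotations of the calls along the genome 102 placed as many on chromosome 2 (permutation p = 0.0103, or 0.216 after multiplying by 21 chromosomes). With edgeR it held 6 calls (adjusted p = 0.732). Runs of 3 neighbouring genes that fell together by DESeq2 were seen in 2 places. They were chromosome 4 from 78458625 to 78715683, with log2 fold changes of -1.44 to -0.75, and chromosome 5 from 155246447 to 155264143, with 3 genes of 3 exons each and -0.66 to -0.54. All 6 genes had separated groups, and 78 of 1000 shuffled gene orders gave as many runs.

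The size of the response was set against other splits of the 8 rats. The real split gave the most calls of the 35, with 38 by edgeR where the highest other split gave 0, and 759 by DESeq2 where the highest other gave 147. Only 1 of 35 splits, the real one, reached each count, which is the least that 35 splits can give. For each count taken alone, chance assignment of rats is disfavoured at 0.05, without adjustment over the other results tested on these splits. Both counts come from the same 8 libraries. Chance assignment was not disfavoured at that level for the tendency of neighbouring genes to move together. The correlation of signed z scores was 0.0995 over 14159 pairs of neighbours that do not overlap, above the highest of 1000 shuffled orders (0.0268), but 2 of 35 splits gave one as high, with 0.104 in the highest other. Genes are not independent replicates in this correlation. Overlapping neighbours, 778 pairs, had 0.244.

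The edgeR calls ended without DMB replicate 1, which could mean that this rat carried them. The fold changes cannot decide this, because the 38 genes were chosen with this rat included and all had separated groups. This comparison was also chosen after the loss of the calls was known. Without DMB replicate 1 the median ratio of the log2 fold changes of the 38 genes to their values with it was 0.983. Such a ratio lay between 0.961 and 1.04 whichever library was left out. Without DMB replicate 1 all 38 genes kept their sign, and their adjusted p lay between 0.0831 and 0.15. Unadjusted p under 0.05 was still reached by 2034 genes against 2584 with all libraries. The calls lay close to the threshold from the start, with 0.0294 as the smallest adjusted p.

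A hypothesis for the chromosome 17 windows was that a family of genes defined by length responded, since 28 of their 48 genes had 1 exon and 1 of 4 lengths. It predicts a rise of genes of these lengths elsewhere. The 17 such genes, on 9 other chromosomes, had a median log2 fold change of 0.19 against 0.17 for other short single-exon genes (one-sided permutation p = 0.437), too few to decide. Another possible explanation, reads moved between near-identical copies inside the windows, predicts no change of their sum. The summed CPM of both windows had a log2 ratio of 0.32 with a standard error of 0.24, which lies above the bound of 0.1 set beforehand by less than that error. Within each rat, the mean log2 CPM relative to log2 of the sum differed by 0.067 with a standard error of 0.041. The mean log2 CPM itself differed by 0.39. This comparison was chosen after the result for the sum was known. By construction, the remainder of the 0.39 is the log2 ratio of 0.32 given above, so the comparison is not separate evidence. Most of the observed increase lay in the sum, but the sum did not differ beyond its spread between rats (exact two-sided permutation test, p = 0.286). A shift of reads between copies therefore stays open.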
